A study of Rattus norvegicus with 192 samples.

How the data were processed

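Gene expression was measured on Illumina rat BeadChip arrays in the prefrontal cortex and hippocampus of adult female Sprague Dawley rats. Per the labels' protocols, pregnant dams received chow (control) or a liquid diet with 36% of its calories from ethanol (ethanol). Pairfed dams received an isocaloric liquid diet without ethanol in the amount an ethanol dam ate. The diets ran from gestation day 1 to day 21. Their daughters were weaned on postnatal day 22. At 50 to 65 days of age they were injected in the skin of the tail base with saline or with 0.1 ml of complete Freund's adjuvant at 12 mg/ml, which induces arthritis. Brains were taken 16 or 39 days after the injection. The litter of each rat and whether vessels were rinsed before dissection are not given in the sources used here, so p-values treat rats as independent.

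The series holds 192 arrays, 96 per tissue, on 16 chips of 12 arrays, with 8 chips per tissue. One array per rat and tissue entered the comparisons, which left 87 prefrontal cortex and 84 hippocampus arrays, and 84 rats gave both tissues. In each tissue the 3 diets, 2 injections and 2 days made 12 groups. Saline groups held 5 rats at day 16 and 6 at day 39, and adjuvant groups held 9, except 8 control and 7 pairfed rats in the hippocampus at day 39. The remaining 20 hybridization replicates and 1 amplification replicate were counted with their rat. For 3 repeat arrays of a single rat the label fields name different injections. The title was followed, and these arrays entered only the spread between repeats and the fits with all arrays. Per the labels' protocols, 250 ng of RNA per sample was amplified in batches of about 24 that were spread over the groups. The batch of each sample is not given in the sources used here.

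Per the file headers, the deposited non-normalized table gives a signal and a detection p-value per probe and array. The deposited signal was read as log2, from the range of its values. The scanner software, the log transform and any background step are not given in the sources used here. The authors' deposited value table is also on the log2 scale. Each of its columns ranked the probes as the raw column of the same array did, 192 of 192 columns matched their own array best, and column medians ran from 7.13 to 7.13 in the prefrontal cortex and from 7.19 to 7.19 in the hippocampus. These values are those of a quantile normalization within each tissue with no background correction, which is inferred from the values alone.

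Here the raw log2 signal was returned to the linear scale, corrected with normexp using the detection p-values, given an offset of 16, quantile-normalized over all arrays and put back on the log2 scale (neqc of limma 3.58.1, in R 4.3.3 with statmod 1.5.0). Folds are therefore on the log2(signal + offset) scale and understate changes of dim probes. Probes with a detection p below 0.05 on at least 5 arrays of a tissue were tested, 15250 in the prefrontal cortex and 15320 in the hippocampus. Of the 22502 probes, 13787 had 1 gene symbol in the platform annotation, 0 had several and 8715 are unnamed here; 13747 of the named probes matched a gene in the current gene table, and 422 genes had more than 1 probe. In the list tests a gene entered with its probe of highest mean signal.

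For each tissue limma fitted the 12 groups with chip as a fixed block, so all groups shared an estimate of the spread. Every comparison averaged over the remaining factors with equal weight, and Benjamini-Hochberg adjustment ran over the probes of a comparison. A probe was called at an adjusted p below 0.05. Differences between the tissues came from a joint limma fit of 171 arrays and 14441 probes with rat as a random block (correlation 0.0327). Tissue levels themselves were not compared, because each chip carried a single tissue. Before the data were examined, 30 gene lists were fixed, 28 written by hand and 2 by symbol rules, for cell types of the brain, tissues next to the dissected regions, blood, stress, immune, metabolic and neuronal functions. They were tested with camera at a preset correlation of 0.01, with adjustment over the 30 lists of a comparison, and again with an estimated correlation and with fry. Also fixed before the data were examined was the rule for named genes: up to 10 rising and 10 falling named probes with the smallest p among those called, the 5 with the smallest p where fewer passed, and up to 4 members with the smallest p from each called list. Genes named outside that rule are said to be.

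The precision is limited by the number of arrays. On simulated data with the real means and spreads and 200 changed probes divided over 3 folds, the prefrontal cortex fit recovered 14.9%, 81.5% and 100% of 1.25-fold, 1.5-fold and 2-fold changes between adjuvant and saline at day 16, against 5.37%, 36.7% and 94.5% between ethanol and control in saline rats and 0%, 0.896% and 20.6% for a difference in adjuvant response between ethanol and control. In the hippocampus the same 3 comparisons gave 16.7%, 71.6% and 97.3%, then 5.97%, 39.4% and 89.1%, then 0%, 1.49% and 20.3%. The folds were set on the offset log2 scale. With fewer changed probes the adjusted cut is stricter, so these rates overstate the recovery of sparse changes. A simulated list of 20 genes shifted by 0.30 on the log2 scale was called in 5 of 5 simulations of the day 16 comparison in each tissue, also with an estimated correlation and by fry. The simulated probes varied independently of each other, so these simulations do not show the power for lists whose members rise and fall together. Alternatives listed before the data were examined were no background correction, median scaling in place of quantile normalization, no detection filter, detection on at least 50% of the arrays, no chip block, chip as a random block, the replicate number as a block, all arrays with rat as a random block, the authors' value table, and each day 16 saline rat left out in turn. Leaving out 2 prefrontal cortex arrays of low signal, leaving out an array in doubt, and the list tests under the other scalings were added after seeing the data. Per the labels, the submitters excluded 1 hippocampus sample of a pairfed adjuvant rat for suspected contamination; it is not analysed here.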

Results

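Gene expression was compared between female rats exposed before birth to ethanol, a pairfed diet or chow, and challenged as adults with complete Freund's adjuvant or saline. The prefrontal cortex was measured in 87 rats and the hippocampus in 84 of them, 16 or 39 days after the injection. A prefrontal cortex array detected 7578 to 10949 probes (median 9868) and a hippocampus array 8140 to 11235 (median 10136). The median correlation of an array with the others of its tissue, across probes, was 0.914 to 0.977 in the prefrontal cortex and 0.937 to 0.974 in the hippocampus. The prefrontal cortex array labelled pairfed saline day 16 replicate 3, kept here as labelled, had a correlation of 0.143 with the hippocampus array of its own rat, over 44 probes that varied with the rat in both tissues. With the hippocampus array of another rat, which is ethanol saline day 16 replicate 5 in the prefrontal cortex, it was 0.809. Replicate numbers differ between the tissues of a rat. Of 84 rats, 82 matched their own hippocampus array best. The other exception was the prefrontal cortex array of ethanol saline day 39 replicate 2, the array with the fewest detected probes. It had 0.583 with its own hippocampus array and 0.638 with that of the same other rat. The 44 probes were chosen on these rats, without the rat of pairfed saline day 16 replicate 3, so a high match rate was partly built in. Differences are given as log2 ± standard error of the limma fit.

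At day 16 the prefrontal cortex of adjuvant rats carried more mRNA of acute phase, stress and blood genes than that of saline rats. The groups held 27 adjuvant and 15 saline rats. S100a8, a subunit of the neutrophil protein calprotectin, rose 3.23-fold (1.69 ± 0.22, limma adjusted p = 4.09e-07). Lcn2, the acute phase protein lipocalin 2, rose 2.39-fold (1.26 ± 0.21, adjusted p = 2.48e-04). Acer2, an alkaline ceramidase, rose 2.23-fold (1.16 ± 0.19) and Tmem252, a transmembrane protein, 2.01-fold (1.01 ± 0.17). Vwf, the von Willebrand factor of endothelial cells and platelets, rose 1.88-fold (0.91 ± 0.14). The hemoglobin gene Hbb-b1 (0.82 ± 0.16), the amino acid transporter Slc38a5 (0.82 ± 0.16) and the glycerol-3-phosphate dehydrogenase Gpd1 (0.81 ± 0.16) rose as well, as did the uridine phosphorylase Upp1 (0.64 ± 0.13) and the zinc finger gene Zfp189 (0.79 ± 0.16). Through the gene lists the hemoglobin gene Hbb (0.79 ± 0.16), the sulfotransferase Sult1a1 (0.70 ± 0.16), Nfkbia, the inhibitor of NF-kappaB (0.59 ± 0.13), and Sgk1, a kinase induced by glucocorticoids (0.48 ± 0.11), joined them. The 4 other named genes that passed, chosen after their values were seen, were Lrg1, an acute phase glycoprotein (0.72 ± 0.15), Ccn2, a matrix growth factor (0.64 ± 0.15), Zswim7 (0.61 ± 0.15) and Mgp, an inhibitor of calcification (0.61 ± 0.13). S100a8 lay above the saline mean in 25 of 27 adjuvant rats and Acer2 in 27 of 27. S100a8 was detected on 24 of 27 adjuvant and 4 of 15 saline arrays, Lcn2 on 19 and 3, Lrg1 on 22 and 2, and Tmem252 on 24 and 3, so the folds of these 4 are set against a level near background and depend on the offset. In all, limma called 20 probes, 19 higher and 1 lower; the lower one and 1 of the higher ones are unnamed. Each of the 18 named genes lay higher in adjuvant rats on 7 or 8 of the 8 chips. The count was 13 without ethanol saline day 16 replicate 5 and 18 without the array labelled pairfed saline day 16 replicate 3, where Sgk1 and Sult1a1 were not called. With the replicate number as a block (replicate block) the count was 0, at a median standard error of 0.208 in place of 0.123. The mean of the hemoglobin probes, a score of blood in the tissue, was 0.68 higher in adjuvant rats. With it as a covariate 3 of the 18 called probes that are not hemoglobin stayed called: S100a8, Vwf and Acer2. With the number of detected probes as a covariate 17 of the 20 stayed called, and Sgk1 (0.47 ± 0.11, adjusted p = 0.0632), Zswim7 (0.62 ± 0.15, adjusted p = 0.0528) and Ccn2 (0.61 ± 0.15, adjusted p = 0.068) did not. With the hemoglobin score the 18 kept a median of 92.4% of their difference (lowest 78.5%), as Nfkbia at 0.61 ± 0.15 and Lrg1 at 0.79 ± 0.17 with larger standard errors.

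**Figure D1:**
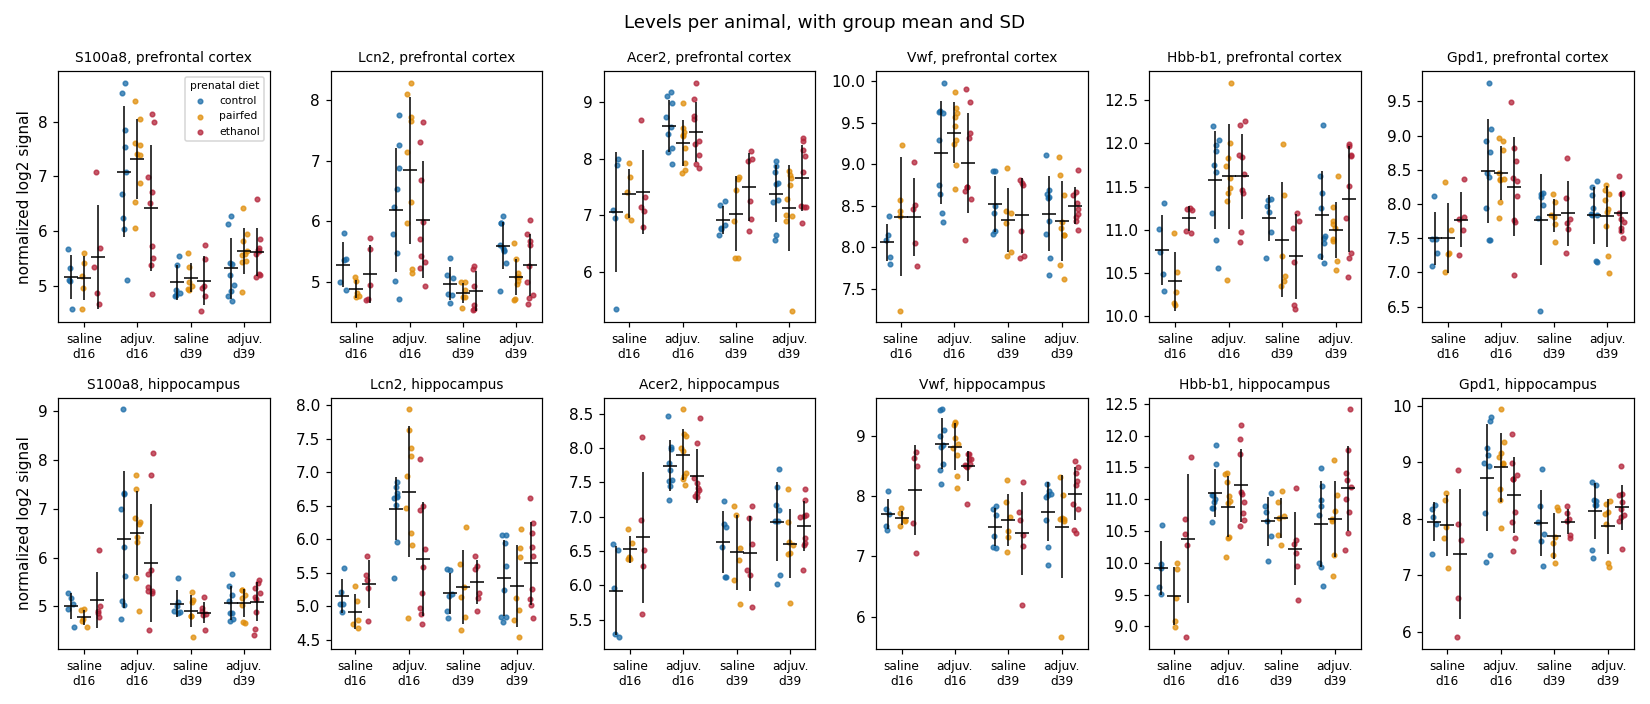
Normalized log2 signal of 6 genes in each rat, by injection and day, in the prefrontal cortex (upper row) and hippocampus (lower row), colored by prenatal diet; bars give the group mean and SD. Adjuvant rats at day 16 lay higher than saline rats, with S100a8, near background in saline rats, up by 1.69 ± 0.22 and 1.31 ± 0.23 in the prefrontal cortex and hippocampus.

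Gene lists fixed in advance placed these genes in groups. List medians depend on the background correction: without it the medians of 41 called lists, relative to all probes, were typically 0.635 times those given, and 23 were smaller by over 1.5 times. Of the blood genes, 8 of 10 lay higher in the prefrontal cortex at day 16 (median log2 0.29, camera adjusted p = 2.05e-10). The list kept its call with an estimated correlation (adjusted p = 2.33e-05), with S100a8, Hbb-b1 and Hbb the 3 members called over all genes and 5 adjusted over the list alone. Of the glucocorticoid and stress axis genes, 16 of 21 lay higher in adjuvant rats (median log2 0.17, camera adjusted p = 1.14e-06). Glucocorticoid and stress axis genes kept the call at adjusted p = 5.34e-04 with an estimated correlation, with 2 members called over all genes and 7 adjusted over the list alone. Sgk1 stood at 0.48 ± 0.11, Sult1a1 at 0.70 ± 0.16, Mt1 at 0.66 ± 0.16 and Per1 at 0.36 ± 0.12. Mt1 is a metallothionein and Per1 a clock gene. Of the acute phase and cytokine genes, 16 of 23 lay higher in adjuvant rats (median log2 0.11, camera adjusted p = 9.39e-06). Acute phase and cytokine genes kept the call at adjusted p = 2.56e-04 with an estimated correlation, with 2 members called over all genes and 4 adjusted over the list alone. Lcn2 stood at 1.26 ± 0.21, Nfkbia at 0.59 ± 0.13, C4b at 0.53 ± 0.16 and Cp at 0.43 ± 0.15. With median scaling the median of the acute phase list was 0.063 relative to all probes, in place of 0.11 (adjusted p = 9.10e-05). C4b is a complement gene and Cp encodes ceruloplasmin. Of the immediate early genes, 20 of 23 lay higher in adjuvant rats (median log2 0.089, camera adjusted p = 1.07e-04). Immediate early genes kept the call at adjusted p = 0.00816 with an estimated correlation, with 0 members called over all genes and 3 adjusted over the list alone. Fos stood at 0.54 ± 0.18, Sik1 at 0.42 ± 0.15, Arc at 0.38 ± 0.17 and Npas4 at 0.32 ± 0.11. These genes follow neuronal activity. Of the heat shock and unfolded protein genes, 21 of 25 lay higher in adjuvant rats (median log2 0.11, camera adjusted p = 0.0025). Heat shock and unfolded protein genes kept the call at adjusted p = 0.00816 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Herpud1 stood at 0.41 ± 0.13, Xbp1 at 0.33 ± 0.12, Creld2 at 0.30 ± 0.11 and Manf at 0.25 ± 0.13. These 4 are genes of endoplasmic reticulum stress. Of the endothelial and mural genes, 6 of 11 lay higher in adjuvant rats (median log2 0.026, camera adjusted p = 0.00966). Endothelial and mural genes lost the call at adjusted p = 0.0836 with an estimated correlation, with 1 member called over all genes and 3 adjusted over the list alone. Vwf stood at 0.91 ± 0.14, Esam at 0.49 ± 0.14, Tagln at 0.69 ± 0.22 and Cspg4 at -0.11 ± 0.15. With median scaling the endothelial median turned to -0.0068 relative to all probes, while the test stayed upward (adjusted p = 0.00694). Of the antigen presentation genes, 14 of 19 lay higher in adjuvant rats (median log2 0.097, camera adjusted p = 0.0111). Antigen presentation genes lost the call at adjusted p = 0.155 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. RT1-A1 stood at 0.99 ± 0.40, RT1-A3 at 0.80 ± 0.36, RT1-Db1 at 0.33 ± 0.16 and Psmb9 at 0.29 ± 0.15.

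Acer2, S100a8 and Lcn2 rose with adjuvant in the hippocampus at day 16, over 27 adjuvant and 15 saline rats. Acer2 rose 2.55-fold (1.35 ± 0.16, limma adjusted p = 6.40e-08) and S100a8 2.49-fold (1.31 ± 0.23). Lcn2 rose 2.17-fold (1.12 ± 0.19) and Vwf 1.97-fold (0.98 ± 0.16). S100a8 was detected on 19 of 27 adjuvant and 1 of 15 saline arrays and Lcn2 on 21 and 4, so their folds are set against a level near background and depend on the offset. The hemoglobin genes Hbb-b1 (1.13 ± 0.18) and Hba-a1 (0.94 ± 0.17), Gpd1 (0.95 ± 0.20) and Slc38a5 (0.88 ± 0.18) rose as well. Tmem252 was detected on 16 of 27 adjuvant and 0 of 15 saline arrays and was at least 1.13-fold higher (adjusted p = 0.0432). That bound was set against the lowest detected signal of each saline array, and Tmem252 was not called without background correction (adjusted p = 0.391). limma called 9 probes, all higher, and each lay higher in adjuvant rats on 6 or 7 of the 7 chips that held both injections. Of these, 8 were also called in the prefrontal cortex, where 0.0125 would be shared by independent lists. Both lists came from the same rats, so they are not independent, and that number is no chance level for them. With median scaling in place of quantile normalization limma called 16 probes, 4 higher and 12 lower, and the median of all probes lay at -0.12. Acer2, S100a8, Lcn2 and Tmem252 stayed called there. The hemoglobin score was 0.90 higher in adjuvant rats, and with it as a covariate 1 of the 7 called probes that are not hemoglobin stayed called, Acer2 (1.03 ± 0.20). S100a8 then stood at 1.30 ± 0.30, Lcn2 at 1.04 ± 0.24, Tmem252 at 0.67 ± 0.17, Gpd1 at 0.79 ± 0.26, Slc38a5 at 0.69 ± 0.22 and Vwf at 0.58 ± 0.18.

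Among gene lists, the blood genes rose in the hippocampus, 9 of 11 higher (median log2 0.29, camera adjusted p = 6.15e-10), with 3 members called over all genes and 5 adjusted over the list alone. Blood genes kept the call at adjusted p = 1.40e-06 with an estimated correlation and with median scaling (adjusted p = 1.23e-08), and Hbb stood at 0.64 ± 0.17. Of the glucocorticoid and stress axis genes, 15 of 21 lay higher in adjuvant rats (median log2 0.13, camera adjusted p = 0.00121). Glucocorticoid and stress axis genes kept the call at adjusted p = 0.00662 with an estimated correlation, with 0 members called over all genes and 5 adjusted over the list alone. Sgk1 stood at 0.50 ± 0.13, Tsc22d3 at 0.44 ± 0.12, Mt1 at 0.58 ± 0.17 and Errfi1 at 0.37 ± 0.13. Median scaling ended that call (adjusted p = 0.235), with the list's median at 0.076 relative to that of all probes. Of the oligodendrocyte and myelin genes, 17 of 19 lay higher in adjuvant rats (median log2 0.10, camera adjusted p = 0.00929). Oligodendrocyte and myelin genes lost the call at adjusted p = 0.524 with an estimated correlation, with 0 members called over all genes and 1 adjusted over the list alone. Cryab stood at 0.65 ± 0.18, Mobp at 0.56 ± 0.23, Plekhb1 at 0.42 ± 0.16 and Nfasc at -0.27 ± 0.17. Of the microglia genes, 10 of 15 lay higher in adjuvant rats (median log2 0.096, camera adjusted p = 0.0463). Microglia genes lost the call at adjusted p = 0.433 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. C1qb stood at 0.39 ± 0.13, C1qa at 0.34 ± 0.12, C1qc at 0.31 ± 0.16 and Ctss at 0.24 ± 0.14. Median scaling ended these calls as well (adjusted p = 0.251 for oligodendrocyte and 0.312 for microglia genes), with medians of 0.076 and 0.086 relative to all probes. Ctss stood at -0.013 there, where the median of all probes lay at -0.12.

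The adjuvant response at day 16 was compared between prenatal diets, over 9 adjuvant and 5 saline rats per diet. S100a8 in the prefrontal cortex differed by 1.96 ± 0.38, 2.20 ± 0.38 and 0.91 ± 0.38 in control, pairfed and ethanol rats. It was detected in only 1, 1 and 2 of the 5 saline rats of these diets, so these values are set against a level near background. For Acer2 in the hippocampus the values were 1.84 ± 0.28, 1.37 ± 0.28 and 0.83 ± 0.28, and in the prefrontal cortex 1.56 ± 0.33, 0.88 ± 0.33 and 1.03 ± 0.33. No probe passed the test of the difference between diets itself. Between ethanol and control rats limma called 0 probes in the prefrontal cortex (812 at an unadjusted p below 0.05, smallest adjusted p 0.49) and 0 in the hippocampus (659, smallest adjusted p 0.204). Between ethanol and pairfed rats it called 0 in the prefrontal cortex (472) and 0 in the hippocampus (564, smallest adjusted p 0.129). Ap1s2 -1.10 ± 0.26, Tex10 -1.48 ± 0.36, Plekha4 -1.65 ± 0.41, Per1 -1.19 ± 0.30 and Rpl27 1.15 ± 0.30 had the smallest p against control in the prefrontal cortex. Eml2 0.97 ± 0.24, Tcf4 0.99 ± 0.27, Kcnj16 -0.97 ± 0.27, Tgfbrap1 0.89 ± 0.27 and Sumf1 -1.13 ± 0.35 had it against pairfed. Cyp11b1 -1.26 ± 0.27, Smyd1 -1.06 ± 0.25, Edn1 -1.35 ± 0.35, Paox -1.11 ± 0.29 and Sike1 -0.93 ± 0.26 had the smallest p against control in the hippocampus. Hmgb3 -1.22 ± 0.31, Cyp11b1 -0.92 ± 0.27, Trip10 -1.14 ± 0.34, Rfesd -1.31 ± 0.39 and Mgp -1.24 ± 0.37 had it against pairfed. The median 95% half-width of such a difference was 0.61 in the prefrontal cortex and 0.63 in the hippocampus on the log2 scale. In simulations 20.6% and 20.3% of 2-fold differences were recovered.

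Some gene lists were called in the test of these differences at the preset correlation, and none with an estimated one. Of the immediate early genes, 16 of 23 lay lower against control in the prefrontal cortex (median log2 -0.25, camera adjusted p = 0.0382). Immediate early genes lost the call at adjusted p = 0.539 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Fos stood at -1.33 ± 0.46, Junb at -0.96 ± 0.35, Arc at -1.12 ± 0.43 and Dusp6 at -0.83 ± 0.32. Of the antigen presentation genes, 14 of 19 lay lower against control there (median log2 -0.17, camera adjusted p = 0.0382). Antigen presentation genes lost the call at adjusted p = 0.539 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Antigen presentation genes also lost it without background correction (adjusted p = 0.0555) and on the authors' values (adjusted p = 0.0546). Their median relative to all probes was -0.27 with median scaling, in place of -0.16 (adjusted p = 0.0303). RT1-A1 stood at -2.97 ± 1.01, RT1-A3 at -2.15 ± 0.91, RT1-T24-4 at -1.66 ± 0.66 and RT1-CE7 at -0.90 ± 0.40. Of the antigen presentation genes, 16 of 19 lay lower against pairfed there (median log2 -0.31, camera adjusted p = 0.0149). The array labelled pairfed saline day 16 replicate 3, which may carry RNA of another rat, entered this comparison. No list test was run without it. Antigen presentation genes lost the call at adjusted p = 0.224 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. RT1-CE7 stood at -0.96 ± 0.40, B2m at -0.45 ± 0.26, Cd74 at -0.74 ± 0.51 and RT1-Da at -0.65 ± 0.46. Of the antigen presentation genes, 15 of 20 lay lower against control in the hippocampus (median log2 -0.47, camera adjusted p = 1.84e-04). Antigen presentation genes lost the call at adjusted p = 0.18 with an estimated correlation, with 0 members called over all genes and 6 adjusted over the list alone. RT1-A1 stood at -3.49 ± 1.09, RT1-Da at -1.87 ± 0.67, RT1-T24-4 at -1.58 ± 0.58 and RT1-DMa at 0.68 ± 0.27. Of the antigen presentation genes, 15 of 20 lay lower against pairfed there (median log2 -0.42, camera adjusted p = 0.0208). Antigen presentation genes lost the call at adjusted p = 0.363 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. RT1-Da stood at -1.65 ± 0.67, RT1-DMa at 0.63 ± 0.27, B2m at -0.58 ± 0.29 and RT1-CE5 at -0.49 ± 0.26.

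Markers of tissue next to the hippocampus were called in the same tests. Of the choroid plexus genes, 13 of 14 lay lower against control (median log2 -0.75, camera adjusted p = 0.00278). Choroid plexus genes lost the call at adjusted p = 0.779 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Ttr stood at -2.80 ± 1.42, Sostdc1 at -2.74 ± 1.47, F5 at -2.33 ± 1.32 and Aqp1 at -1.77 ± 0.90. Ttr encodes transthyretin. Of the choroid plexus genes, 12 of 14 lay lower against pairfed (median log2 -0.45, camera adjusted p = 0.00359). Choroid plexus genes lost the call at adjusted p = 0.465 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Ttr stood at -2.95 ± 1.42, Sostdc1 at -3.43 ± 1.47, F5 at -2.96 ± 1.32 and Aqp1 at -1.64 ± 0.90. Of the meninges genes, 11 of 13 lay lower against control (median log2 -0.61, camera adjusted p = 0.00499). Meninges genes lost the call at adjusted p = 0.779 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Slc6a13 stood at -0.65 ± 0.30, Cyp1b1 at -0.67 ± 0.36, Fmod at -1.14 ± 0.64 and Col3a1 at -0.61 ± 0.34. Of the meninges genes, 12 of 13 lay lower against pairfed (median log2 -0.66, camera adjusted p = 0.00133). Meninges genes lost the call at adjusted p = 0.363 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Ptgds stood at -1.14 ± 0.47, Slc6a13 at -0.66 ± 0.30, Ogn at -1.41 ± 0.75 and Slc22a6 at -0.90 ± 0.50. Of the striatum genes, 9 of 10 lay lower against pairfed (median log2 -0.32, camera adjusted p = 0.0282). Striatum genes lost the call at adjusted p = 0.465 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Penk stood at -1.18 ± 0.48, Adora2a at -0.98 ± 0.64, Drd2 at -0.59 ± 0.40 and Drd1 at -0.53 ± 0.48. Of the thalamus genes, 11 of 11 lay lower against pairfed (median log2 -0.28, camera adjusted p = 0.0259). Thalamus genes lost the call at adjusted p = 0.465 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Thalamus genes also lost it without background correction (adjusted p = 0.0542) and on the authors' values (adjusted p = 0.0549). Tcf7l2 stood at -0.68 ± 0.40, Prkcd at -1.66 ± 1.16, Tnnt1 at -0.35 ± 0.28 and Calb2 at -0.48 ± 0.46.

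By day 39 no gene passed between adjuvant and saline rats in either tissue. The groups held 27 adjuvant and 18 saline rats in the prefrontal cortex and 24 and 18 in the hippocampus. S100a8 stood at 0.43 ± 0.21, Lcn2 at 0.44 ± 0.20, Acer2 at 0.26 ± 0.18 and Vwf at 0.029 ± 0.13 in the prefrontal cortex. Acer2 stood at 0.29 ± 0.16 and S100a8 at 0.091 ± 0.23 in the hippocampus. limma called 0 probes in the prefrontal cortex (814 at an unadjusted p below 0.05) and 0 in the hippocampus (770). Suox -0.59 ± 0.14, Ube3a -0.39 ± 0.097, Cyp20a1 0.61 ± 0.16, Rwdd4 0.38 ± 0.10 and Irx3 -0.42 ± 0.11 had the smallest p in the prefrontal cortex. Tmem132e -0.58 ± 0.15, Dync1i1 -0.39 ± 0.10, Spaca9 0.55 ± 0.15, Kcnc1 -0.43 ± 0.11 and Rnls -0.44 ± 0.12 had it in the hippocampus. No gene's response was shown to differ between the days: at day 39 minus day 16, Vwf in the prefrontal cortex had -0.88 ± 0.19 (adjusted p = 0.229). S100a8 had -1.26 ± 0.30 there (adjusted p = 0.314), and Acer2 in the hippocampus -1.06 ± 0.23 (adjusted p = 0.207). The response of the blood list in the hippocampus was lower at day 39 than at day 16 (median difference -0.38, camera adjusted p = 1.58e-05; adjusted p = 5.48e-04 with an estimated correlation). So was that of the glucocorticoid list (-0.21, adjusted p = 0.00398; adjusted p = 0.0161 with an estimated correlation). The glucocorticoid list of the prefrontal cortex had -0.14 (adjusted p = 0.00476), a call lost at adjusted p = 0.104 with an estimated correlation.

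**Figure D2:**
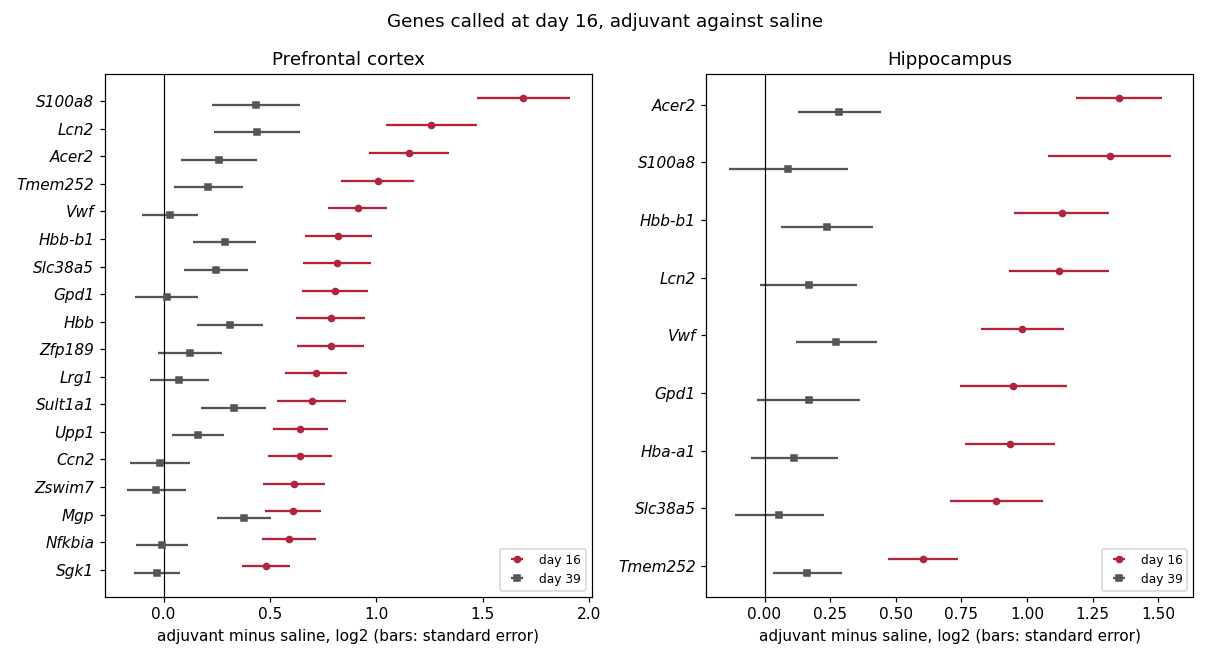
Adjuvant minus saline difference (log2, bars give the standard error) of the named genes called at day 16, at day 16 (circles) and day 39 (squares), in the prefrontal cortex (left) and hippocampus (right). In the prefrontal cortex S100a8, near background in saline rats, stood at 1.69 ± 0.22 at day 16 and 0.43 ± 0.21 at day 39.

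At day 39 camera called 4 lists in the prefrontal cortex and 2 in the hippocampus, and none held with an estimated correlation. Of the blood genes, 9 of 10 lay higher in the prefrontal cortex (median log2 0.20, camera adjusted p = 0.00141). Blood genes lost the call at adjusted p = 0.0578 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Hba-a1 stood at 0.37 ± 0.13, Hbb at 0.31 ± 0.15 and Hbb-b1 at 0.29 ± 0.15. The adjusted p of fry for blood genes was 0.0472. Of the meninges genes, 12 of 13 lay higher there (median log2 0.13, camera adjusted p = 0.00339). Meninges genes lost the call at adjusted p = 0.181 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Slc6a13 stood at 0.40 ± 0.15, Col1a2 at 0.28 ± 0.12, Igf2 at 0.27 ± 0.13 and Fmod at 0.34 ± 0.19. Of the microglia genes, 12 of 15 lay higher there (median log2 0.15, camera adjusted p = 0.00729). Microglia genes lost the call at adjusted p = 0.181 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Laptm5 stood at 0.29 ± 0.13, Itgam at 0.22 ± 0.12, P2ry13 at 0.26 ± 0.15 and C1qc at 0.23 ± 0.13. Of the antigen presentation genes, 12 of 19 lay higher there (median log2 0.058, camera adjusted p = 0.00681). Antigen presentation genes lost the call at adjusted p = 0.181 with an estimated correlation, with 0 members called over all genes and 3 adjusted over the list alone. Cd74 stood at 0.70 ± 0.19, RT1-Da at 0.61 ± 0.17, RT1-Ba at 0.57 ± 0.18 and Psmb8 at 0.32 ± 0.13. Cd74 is the invariant chain of class II molecules. Of the choroid plexus genes, 14 of 14 lay higher in the hippocampus (median log2 0.32, camera adjusted p = 8.57e-06). Choroid plexus genes lost the call at adjusted p = 0.422 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Ttr stood at 1.20 ± 0.57, Trpv4 at 0.56 ± 0.28, Kcne2 at 0.27 ± 0.14 and Prlr at 0.23 ± 0.12. Of the oligodendrocyte and myelin genes, 16 of 19 lay higher there (median log2 0.18, camera adjusted p = 0.00101). Oligodendrocyte and myelin genes lost the call at adjusted p = 0.422 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Median scaling ended the call at day 39 (adjusted p = 0.0942, 11 of 19 higher), with the list's median at 0.11 relative to that of all probes (-0.099). Mbp stood at 0.63 ± 0.29, Mog at 0.31 ± 0.15, Aspa at 0.30 ± 0.15 and Mobp at 0.37 ± 0.23.

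Meninges genes lay lower as a list in the prefrontal cortex of saline rats at day 39 than at day 16. These were different rats (15 at day 16 and 18 at day 39), which differ in age and in time since injection. Uneven carry-over of meninges in dissection was not tested. The same day 39 saline rats were the reference for the higher meninges list of adjuvant rats at day 39. Of the meninges genes, 13 of 13 lay lower at day 39 (median log2 -0.24, camera adjusted p = 4.22e-06). Meninges genes kept the call at adjusted p = 0.0474 with an estimated correlation, with 0 members called over all genes and 2 adjusted over the list alone. Col1a2 stood at -0.60 ± 0.13, Igf2 at -0.44 ± 0.15, Fmod at -0.49 ± 0.21 and Ptgds at -0.23 ± 0.13. Col1a2 encodes a collagen and Igf2 a growth factor. No single gene passed. limma called 0 probes in the prefrontal cortex (855 at an unadjusted p below 0.05). Shisa3 -0.98 ± 0.22, Col1a2 -0.60 ± 0.13, Timp1 -0.82 ± 0.19, Cpxm2 -0.75 ± 0.19 and Hnmt 0.46 ± 0.12 had the smallest p there. It called 0 in the hippocampus (1307 at an unadjusted p below 0.05, against 766 by chance), where 154 probes had an adjusted p below 0.25. Dhx16 -0.64 ± 0.13, Uimc1 -0.68 ± 0.15, Braf -0.68 ± 0.16, Fbxl20 -1.55 ± 0.37 and Kmt5c -0.87 ± 0.21 had the smallest p there. With all arrays and rat as a random block limma called 16 probes in the hippocampus, 2 higher and 14 lower.

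The steady state after prenatal ethanol was read in saline rats as the mean of the day 16 and day 39 differences, over 11 rats per diet. No gene passed between the diets in either tissue. Ap1s2, of a clathrin adaptor, stood at 0.58 ± 0.14 and Top3b, a topoisomerase, at 0.56 ± 0.13 between ethanol and control in the prefrontal cortex. Alox12 -0.54 ± 0.15, Rin3 -0.49 ± 0.14 and Papss1 0.45 ± 0.13 followed, and limma called 0 probes (789 at an unadjusted p below 0.05, smallest adjusted p 0.624). Bcl2l11 0.54 ± 0.13, Mgat2 -0.56 ± 0.16, Idi1 -0.48 ± 0.14, Etv1 0.57 ± 0.17 and Emg1 -0.54 ± 0.16 had the smallest p between ethanol and pairfed, with 0 called (640). Pcsk4 0.87 ± 0.18, Olr1633 0.48 ± 0.13, Plagl2 0.45 ± 0.12, Orc6 0.58 ± 0.16 and Zfp219 0.59 ± 0.17 had it between pairfed and control, with 0 called (784, smallest adjusted p 0.0945). Without control saline day 16 replicate 2 the count between pairfed and control was 3. Cyp11b1 0.57 ± 0.15, Zfp746 0.74 ± 0.20, Inppl1 -0.65 ± 0.18, Pcmtd2 0.64 ± 0.20 and Paox 0.51 ± 0.16 had the smallest p between ethanol and control in the hippocampus. Zfp868 -0.62 ± 0.17, Trim26 0.53 ± 0.16, Cpa3 -0.46 ± 0.14, Retsat -1.03 ± 0.31 and Chst10 -0.51 ± 0.16 had it between ethanol and pairfed, and Sox11 0.77 ± 0.19, Paox 0.60 ± 0.16, Mllt3 -0.55 ± 0.16, Rab6b 0.42 ± 0.13 and Ahi1 0.57 ± 0.17 between pairfed and control. limma called 0 probes in each of these 3 (469, 393 and 471 at an unadjusted p below 0.05, against 766 by chance). Retsat also varied between rats alike in both tissues once group and chip were removed (correlation 0.628). The median 95% half-width of a diet difference was 0.33 in the prefrontal cortex and 0.34 in the hippocampus on the log2 scale. On the offset log2 scale the 95% interval of ethanol against control lay within a 2-fold change for 99.2% and 99% of tested probes. These include dim probes, whose changes that scale understates, so a true 2-fold change is not excluded for them. Of the ribosomal protein genes, 47 of 65 lay lower in ethanol than in pairfed rats of the prefrontal cortex (median log2 -0.085, camera adjusted p = 0.0169). Ribosomal protein genes lost the call at adjusted p = 0.736 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Relative to all probes the list lay at -0.17 with median scaling, in place of -0.084 (adjusted p = 5.10e-05). Rpl22 stood at -0.49 ± 0.15, Rplp1 at -0.36 ± 0.14, Rpl35 at -0.49 ± 0.20 and Rpl27 at -0.36 ± 0.16.

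After adjuvant the diets were compared as the mean of both days, over 18 rats per diet in the prefrontal cortex and 16 to 18 in the hippocampus, and no gene passed. Dio2 -0.57 ± 0.15, Slc13a3 0.58 ± 0.15, Or4l1 0.36 ± 0.099, Dpys -0.35 ± 0.098 and Hcfc2 0.49 ± 0.14 had the smallest p between ethanol and control in the prefrontal cortex. Dio2 is a deiodinase of thyroid hormone. Zfp84 -0.59 ± 0.16, Nxpe1 0.46 ± 0.13, Slc13a3 0.53 ± 0.15, Pus10 0.43 ± 0.13 and Gid8 -0.57 ± 0.17 had it between ethanol and pairfed. Oat -0.36 ± 0.090, Npas4 -0.45 ± 0.11, Rap1gds1 -0.82 ± 0.21, Bola1 0.56 ± 0.15 and Zp1 -0.42 ± 0.11 had it between pairfed and control. limma called 0 probes in each (767, 480 and 686 at an unadjusted p below 0.05). In the hippocampus Cyp1b1, a cytochrome P450, stood at -0.68 ± 0.15 and Cited2 at -0.56 ± 0.13 between ethanol and control (adjusted p = 0.21 for each). Hnrnpk -0.46 ± 0.12, Ddx46 -0.53 ± 0.14 and Slc25a15 0.62 ± 0.17 followed. The ribosomal protein gene Rps14 stood at 0.68 ± 0.14 between ethanol and pairfed (adjusted p = 0.109). Pcdhac2 -0.72 ± 0.17, Tbl3 -0.62 ± 0.15, Aplp1 -0.56 ± 0.14 and Ccp110 -0.61 ± 0.16 followed. Trim25 -0.60 ± 0.13, Capn11 -0.52 ± 0.12, Defb1 -0.49 ± 0.13, Tnf 0.41 ± 0.11 and Lrrc14 0.54 ± 0.14 had the smallest p between pairfed and control, the smallest adjusted p being 0.136. limma called 0 probes in each (923, 1048 and 863 at an unadjusted p below 0.05), and 2 between ethanol and pairfed on the authors' value table, where Rps14 passed (adjusted p = 0.0491).

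Between the diets of adjuvant rats several lists were called at the preset correlation, and none with an estimated one. Of the ribosomal protein genes, 47 of 65 lay higher in ethanol than in control rats of the hippocampus (median log2 0.084, camera adjusted p = 0.00232). Ribosomal protein genes lost the call at adjusted p = 0.726 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Rplp1 stood at 0.36 ± 0.14, Rpl13a at 0.35 ± 0.14, Rpl4 at 0.29 ± 0.12 and Rpl9 at 0.35 ± 0.15. Of the ribosomal protein genes, 42 of 65 lay higher in ethanol than in pairfed rats there (median log2 0.10, camera adjusted p = 0.0114). Ribosomal protein genes lost the call at adjusted p = 0.43 with an estimated correlation, with 0 members called over all genes and 1 adjusted over the list alone. Rps14 stood at 0.68 ± 0.14, Rpl13a at 0.44 ± 0.14, Rps12 at 0.43 ± 0.16 and Rplp1 at 0.34 ± 0.14. Of the mitochondrial respiratory chain genes, 46 of 69 lay higher in ethanol than in pairfed rats there (median log2 0.051, camera adjusted p = 0.0414). Mitochondrial respiratory chain genes lost the call at adjusted p = 0.43 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Ndufa7 stood at 0.35 ± 0.13, Ndufb6 at 0.42 ± 0.16, Ndufaf5 at 0.24 ± 0.099 and Ndufa11 at 0.26 ± 0.11. Ndufaf5 is an assembly factor of complex I. With median scaling these 3 calls ended, at adjusted p = 0.0767, 0.237 and 0.584. Relative to the median of all probes (-0.040 and -0.046 against control and pairfed) their medians then lay at 0.064, 0.065 and 0.012. Of the striatum genes, 10 of 10 lay lower in ethanol than in pairfed rats there (median log2 -0.26, camera adjusted p = 0.0114). Striatum genes lost the call at adjusted p = 0.43 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Drd2 stood at -0.36 ± 0.18, Pde10a at -0.29 ± 0.15, Pde1b at -0.27 ± 0.17 and Rgs9 at -0.37 ± 0.24. Of the striatum genes, 10 of 10 lay higher in pairfed than in control rats there (median log2 0.33, camera adjusted p = 2.91e-04). Striatum genes lost the call at adjusted p = 0.402 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Pde1b stood at 0.49 ± 0.17, Pde10a at 0.38 ± 0.16, Ppp1r1b at 0.33 ± 0.17 and Drd2 at 0.34 ± 0.18. Drd2 is a dopamine receptor. Of the oligodendrocyte and myelin genes, 15 of 19 lay higher in pairfed than in control rats of the prefrontal cortex (median log2 0.096, camera adjusted p = 0.0419). Oligodendrocyte and myelin genes lost the call at adjusted p = 0.79 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Ugt8 stood at 0.25 ± 0.13, Olig1 at 0.22 ± 0.12, Plekhb1 at 0.24 ± 0.13 and Cryab at 0.23 ± 0.15. Of the ribosomal protein genes, 50 of 65 lay higher in pairfed than in control rats there (median log2 0.058, camera adjusted p = 0.0419). Ribosomal protein genes lost the call at adjusted p = 0.79 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. Rpl27 stood at 0.31 ± 0.12, Rpl35a at 0.32 ± 0.14, Rps25 at 0.31 ± 0.16 and Rps3a at 0.23 ± 0.13. These lists lay farther from 0 with median scaling, at 0.23 for oligodendrocyte and 0.19 for ribosomal protein genes relative to all probes, in place of 0.088 and 0.051 (adjusted p = 0.00352 and 1.06e-07).

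The response to adjuvant was not shown to differ between the tissues for any gene. The day 16 response of S100a8 in the prefrontal cortex minus that in the hippocampus was 0.38 ± 0.32, that of Lcn2 0.14 ± 0.29 and that of Acer2 -0.19 ± 0.25. For this response limma called 0 probes (673 at an unadjusted p below 0.05). Anxa8 0.54 ± 0.15, Napa -0.53 ± 0.14, Pola2 0.73 ± 0.20, Tmem200a 0.83 ± 0.23 and Cct4 0.50 ± 0.15 had the smallest p. For ethanol against control it called 0 in saline rats (578) and 0 in adjuvant rats (674). Cyp11b1 -0.80 ± 0.19, Ccnb1ip1 0.75 ± 0.19, Ubqln1 -0.79 ± 0.21, Abat -0.93 ± 0.25 and Spsb3 -0.69 ± 0.19 had the smallest p in saline rats. Cog3 -0.69 ± 0.19, Or4l1 0.50 ± 0.14, Or2a25 -0.60 ± 0.17, Naaa 0.71 ± 0.21 and Cyp1b1 0.73 ± 0.21 had it in adjuvant rats.

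Other gene lists passed in no comparison within a tissue. Their smallest camera adjusted p was 0.0802 for astrocyte, 0.185 for oligodendrocyte precursor, 0.0547 for pan-neuronal, 0.0614 for glutamatergic neuron and receptor and 0.145 for GABAergic neuron and receptor genes. It was 0.0547 for interferon response, 0.3 for circadian, 0.186 for oxidative stress, 0.0614 for alcohol and aldehyde metabolism and 0.426 for cholesterol synthesis genes. For the remaining lists it was 0.244 for monoamine and acetylcholine signalling, 0.0906 for neurotrophin and growth factor, 0.163 for neurogenesis and cell cycle, 0.272 for DNA methylation and chromatin and 0.49 for estrogen and pituitary or hypothalamic hormone genes.

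Repeat hybridizations of the same RNA gave the measurement error. Over 9 arrays of a single prefrontal cortex RNA the median SD of a probe was 0.34, against 0.39 between rats of a group. Over 4 arrays each of 4 hippocampus RNAs it was 0.27 to 0.35, against 0.41. As a ratio of medians over probes, the variance between repeats was thus 74.9% of that between rats in the prefrontal cortex and 43.3% to 73.3% in the hippocampus. A median variance from few arrays runs low. The hippocampus ratios, from 4 arrays each, are therefore not comparable with that from 9 arrays. A repeated amplification of 1 prefrontal cortex RNA gave a median SD of 0.21 over 2 arrays. These 2 arrays shared a chip while the hybridization repeats lay on several, so this value is not comparable with those above.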

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

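Among the tests of this part, the correlation within the choroid plexus list and the match of a prefrontal cortex array to its own rat were chosen after the results were seen. For the tests with a covariate the bound set in advance was on the median of the probes; that all of them lie above it was required only after the results were seen, which left the hippocampus undecided for blood. A sample lay far from the others of its group in 10 of 162 groups of values; chance gives about 1 in 20 groups. In the prefrontal cortex the log2 level of Acer2 in ethanol saline day 16 replicate 3 was 8.68, against 6.79 to 7.33 in the other 4 rats. Its Tmem252 level was 7.07, against 4.81 to 5.20 in the other 4 rats. The Upp1 level of control adjuvant day 16 replicate 3 was 9.67, against 8.23 to 8.85 in the other 8 rats. The Tmem252 level of pairfed adjuvant day 16 replicate 2 was 5.37, against 6.19 to 6.98 in the other 8 rats. The number of detected probes in ethanol saline day 39 replicate 2 of the prefrontal cortex was 7578, against 9451 to 10535 in the other 5 rats. In control adjuvant day 39 replicate 3 of that tissue it was 7905, against 9243 to 10462 in the other 8 rats. In the hippocampus the Hba-a1 level of control saline day 16 replicate 3 was 11.27, against 12.21 to 12.51 in the other 4 rats. The number of detected probes in ethanol saline day 16 replicate 1 was 9227, against 10588 to 10892 in the other 4 rats. The S100a8 level of ethanol saline day 16 replicate 4 was 6.15, against 4.78 to 5.00 in the other 4 rats. The Vwf level of ethanol adjuvant day 16 replicate 7 was 7.87, against 8.48 to 8.69 in the other 8 rats.

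The response of some gene lists differed between groups by the camera test of the difference at the preset correlation; values are the median log2 difference of the members. For the day 16 adjuvant response of ethanol against control rats it was -0.25 for immediate early genes and -0.17 for antigen presentation genes in the prefrontal cortex. It was -0.75 for choroid plexus, -0.61 for meninges and -0.47 for antigen presentation genes in the hippocampus. Against pairfed rats it was -0.31 for antigen presentation genes in the prefrontal cortex, and -0.45 for choroid plexus, -0.66 for meninges, -0.32 for striatum, -0.28 for thalamus and -0.42 for antigen presentation genes in the hippocampus. The response at day 39 minus that at day 16 was -0.14 for glucocorticoid genes in the prefrontal cortex, and 0.26 for choroid plexus, -0.38 for blood and -0.21 for glucocorticoid genes in the hippocampus. The prefrontal cortex response at day 16 exceeded that of the hippocampus by 0.19 for immediate early genes. With an estimated correlation the blood and glucocorticoid differences between the days in the hippocampus kept their call (adjusted p = 5.48e-04 and 0.0161), the others within a tissue lost it, and for the difference between tissues only the preset correlation was run. The prefrontal cortex array of ethanol saline day 39 replicate 2, with the fewest detected probes, correlated at 0.583 with its own hippocampus array. It correlated at 0.638 with the hippocampus array of the rat that is ethanol saline day 16 replicate 5 in the prefrontal cortex.

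The genes that rose at day 16 include hemoglobin genes, so blood left in the vessels could account for them. With the hemoglobin score as a covariate, the 18 other called probes of the prefrontal cortex kept a median of 92.4% of their difference (lowest 78.5%). Among well detected genes, Vwf went from 0.91 ± 0.14 to 0.91 ± 0.17 and Acer2 from 1.16 ± 0.19 to 1.09 ± 0.22. Mgp, the lowest, went from 0.61 ± 0.13 to 0.48 ± 0.16. For well detected genes this argues against red cells as the whole cause, as far as the score follows blood. S100a8 went from 1.69 ± 0.22 to 1.66 ± 0.26. It, Lcn2, Lrg1 and Tmem252 were near background in saline rats of that tissue and exclude little. In all, 15 calls ended as the standard errors rose and some differences shrank. In the hippocampus the 7 other probes kept a median of 83%, from 58.7% to 111%: S100a8 (1.31 ± 0.23 to 1.30 ± 0.30), Lcn2 (1.12 ± 0.19 to 1.04 ± 0.24) and Tmem252 (0.60 ± 0.13 to 0.67 ± 0.17) lost their call mainly as the standard errors rose, and Vwf (0.98 ± 0.16 to 0.58 ± 0.18) as its difference shrank, while Acer2 (1.35 ± 0.16 to 1.03 ± 0.20) stayed called. The lost calls of the former 3 are thus no evidence for blood, but these genes were near background in saline rats there and exclude little, so a part of blood in the hippocampus stays open. With the number of detected probes as a covariate the called probes kept 99.3% and 107%, which argues against array quality as the whole cause though Sgk1, Zswim7 and Ccn2 of the prefrontal cortex lost their call (0.48 to 0.47, 0.61 to 0.62 and 0.64 to 0.61), while white cells held in vessels, which the hemoglobin score does not follow, and a response of the brain to adjuvant stay open.

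The prefrontal cortex array labelled pairfed saline day 16 replicate 3 may carry RNA of another rat. Over the probes that follow the rat in both tissues, its correlation with its own hippocampus array was 0.143. It was 0.809 with the hippocampus array of the rat that is ethanol saline day 16 replicate 5 in the prefrontal cortex. The prefrontal cortex array of that rat itself gave 0.808 with the same hippocampus array. The prefrontal cortex arrays of both correlated at 0.902 over these probes, above every other pair of rats (highest 0.84), which favors RNA of that rat, though a close relative is not excluded, since litters are not given in the sources used here. Over the remaining probes, with group and chip removed, they correlated at 0.129, within the range of other pairs (highest 0.227) and so past the bound set in advance against RNA hybridized again. With chip alone removed it was 0.128 (other pairs up to 0.256), where known repeats of a single RNA gave only 0.00442 to 0.25, so that test cannot decide, and no biological explanation was tested.

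Choroid plexus genes gave the largest median shift among the lists above, -0.75 in the hippocampus, which was -0.34 without background correction and -0.34 on the authors' values. Their estimated correlation between members within groups was 0.523, so the members rose and fell together between rats of a group, in line with uneven carry-over of choroid plexus in dissection. That correlation would also arise from a choroid plexus response that varied between rats, so an effect of prenatal ethanol stays open, untested.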

How the results depend on the processing

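The list tests under other scalings and the fits without doubtful arrays were chosen after seeing the data. List tests were not repeated without the array labelled pairfed saline day 16 replicate 3 or without the 2 arrays of lowest signal. Of 25 counts of called probes, 481 values under an alternative stayed within 1.5 times the count reported and 9 moved. All but the day 16 adjuvant counts, 20 in the prefrontal cortex and 9 in the hippocampus, were 0 as reported. A 0 that stayed 0 was taken as unmoved, so the 481 are mostly such values and say little about stability. With the replicate block 0 probes were called by limma in the prefrontal cortex at day 16 (997 at an unadjusted p below 0.05). There the median standard error was 0.208 in place of 0.123, Cspg4 stood at 0.40, Sik1 at -0.20 and Manf at -0.19. Arrays of the same number had a mean correlation of 0.0259 in the prefrontal cortex, against -0.00333 for other pairs, and of -0.0304 once chip was removed. In the hippocampus it was 0.058 against -0.008, and 0.0515 once chip was removed, so arrays of a number stayed slightly alike there. What the number stands for is not stated in the sources used here. In the prefrontal cortex it rose along the chips within each group, and the smaller saline groups lacked the highest numbers. With chip also fitted, the replicate block thus overlapped in part with the injection. Its 0 calls there cannot tell an unstable response from lost precision. With median scaling 16 were called in the hippocampus at day 16, and Ctss stood at -0.013. It moved the median of all probes to -0.12 there, -0.10 for the difference in response of ethanol and control rats in the prefrontal cortex and 0.19 for the day 16 response between tissues. From the authors' values 2 probes were called in the hippocampus between ethanol and pairfed adjuvant rats and 1 for their day 16 response. With no detection filter it was 1 for the response of ethanol against control rats in the prefrontal cortex. With all arrays and rat as a random block it was 16 between the days in saline rats of the hippocampus. Leaving out each day 16 saline rat gave 13 to 23 at day 16 in the prefrontal cortex (13 without ethanol saline day 16 replicate 5), 6 to 10 in the hippocampus. It gave 0 to 3 between pairfed and control saline rats of the prefrontal cortex (3 without control saline day 16 replicate 2) and 0 to 1 for the response of ethanol against pairfed rats in the hippocampus (1 without pairfed saline day 16 replicate 4). Of 41 called lists, 7 lost their call with median scaling, 2 with no background correction and 2 on the authors' table. Relative to all probes, their medians were 0.322 to 0.973 times those reported without background correction, 23 of them smaller by over 1.5 times, and 0.319 to 0.968 times on the authors' values, 23 smaller. With median scaling they were -0.28 to 3.8 times those reported, 6 smaller and 4 larger by over 1.5 times. Among 273 named genes, 2623 values kept side and direction, 30 lost a call, 12 gained one and 4 turned, as given above. The cause was not tested. The 2 arrays of lowest signal limit dim probes; without them 23 probes were called in the prefrontal cortex at day 16, 20 of them the same.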

Other observations

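The percentile of the antigen presentation list was a test chosen after the result was seen, and the genes of this paragraph were named after their values were seen. Some genes differed between rats alike in both tissues once group and chip were removed. In 83 rats, 44 of 14441 probes had a correlation over 0.6 between the tissues, 39 of them by rank as well, 28 named; in 100 permutations of the rats the largest number was 0. Among them, with the SD between rats in log2 units for the prefrontal cortex and hippocampus, were Spock2 (1.33 and 1.53), a proteoglycan gene, Ephx2 (0.93 and 0.99), a soluble epoxide hydrolase, Rps9 (2.03 and 1.94) and Rpl30 (1.36 and 1.44), of the ribosome. Others were RT1-A1 (1.18 and 1.29), a class I antigen presentation gene, Slc39a12 (0.91 and 1.13), a zinc transporter, and Pxmp4 (1.07 and 1.13), of the peroxisome. S100a8, called at day 16, was among them too, with SDs of 0.64 and 0.66.

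Inherited differences between outbred rats may contribute to the antigen presentation shifts. The median correlation of the list's 19 members between tissues was 0.128, at percentile 99.6 of 10000 random lists of the same size, and 3 members exceeded 0.6. Any state shared by both tissues of a rat would raise this correlation, so it cannot single out inheritance. S100a8, which rose with adjuvant, exceeded 0.6 as well (0.71). For single genes with the smallest p in diet comparisons 1 of 56 exceeded 0.6, fewer than the 3 set in advance. It was Retsat (0.628). From all named probes, though, 0.157 would be expected. The hypothesis was thus not borne out for these genes as a set and stays open for that 1. An effect of diet on antigen presentation stays open, and litters are not given in the sources used here.

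Each comparison was repeated on 100 splits of the same rats into groups of the same sizes, the real one included; the numbers below are the splits with a result as large. For called probes at day 16 it was 1 (real 20, highest other 1) in the prefrontal cortex, so no other split came near the real count. A share of 1 in 100 is the lowest that these splits can give. Over 25 comparisons that share alone does not exclude chance, and rats were taken as independent. In the hippocampus the number of such splits for called probes was 3 (real 9, highest other 312). That share lay below the bound set in advance for a comparison taken alone. A random split could call far more probes than the real one, so chance is not excluded there. The many probes of that highest split were not explained, so the count of called probes there is weak evidence. For the rest the result is the number of probes at an unadjusted p below 0.05. Between the days in saline rats of the hippocampus it was 4 (real 1307, highest other 1742). That share too lay below the bound for a comparison taken alone. Chance is not excluded, since 25 comparisons were tested so and limma called 0 probes in this comparison. In the prefrontal cortex it was 50 (real 855, highest other 1242). Chance cannot be excluded there or in the comparisons that follow. In saline rats of the prefrontal cortex it was 75 (real 789, highest other 1286) for ethanol against control, 91 (real 640, highest other 1190) for ethanol against pairfed and 57 (real 784, highest other 1303) for pairfed against control. In adjuvant rats of that tissue it was 49 (real 767, highest other 1049), 91 (real 480, highest other 1333) and 59 (real 686, highest other 970). In the hippocampus the same comparisons gave 74 (real 469, highest other 1495), 95 (real 393, highest other 1568) and 93 (real 471, highest other 1236) in saline rats. There it was 29 (real 923, highest other 1458), 16 (real 1048, highest other 1348) and 47 (real 863, highest other 1703) in adjuvant rats. At day 39 adjuvant against saline gave 57 (real 814, highest other 1464) in the prefrontal cortex and 33 (real 770, highest other 1033) in the hippocampus. The day 16 response of ethanol against control rats gave 10 (real 812, highest other 963) and 59 (real 659, highest other 2347) in these tissues, and against pairfed rats 61 (real 472, highest other 795) and 51 (real 564, highest other 2399). For prefrontal cortex minus hippocampus it was 76 (real 578, highest other 1095) for ethanol against control in saline rats, 83 (real 674, highest other 1306) in adjuvant rats and 38 (real 673, highest other 1150) for the day 16 response.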
